A study of Mus musculus with 4 samples.

How the data were processed

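Early mouse blastocysts made by IVF or by SCNT were compared by RNA-seq, with 2 libraries per group and 6 embryos per library. Per the labels' protocols, embryos were lysed directly, cDNA was made and amplified with a SMARTer Ultra Low Input kit, the cDNA was sheared on a Covaris sonicator, and libraries were made with a NEBNext Ultra DNA kit. Such pooling averages over embryos, and amplification from few cells adds noise to low genes. Samples were grouped by their titles. Per the file headers, the columns of the SCNT libraries carry the name of Kdm4d, a histone demethylase gene, which the labels do not mention; whether these embryos were treated with it is not given in the sources used here. Kdm4d itself was listed at 0 and 0.0382 FPKM in IVF and at 0.0649 and 0.117 FPKM in SCNT.

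The values deposited by the authors were taken to be FPKM, 1 value per gene symbol for 23235 symbols in each library. That unit is inferred, from Cufflinks among the tools in the submitters' processing notes and from the values themselves, since per the file headers the columns hold only an identifier and a library name. Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.1.0 and Cufflinks 2.2.1 were used with the mm9 build of the mouse genome. The annotation, the parameters, any filter, the use of strand and any scaling between libraries are not given in the sources used here. FPKM of very short genes is unstable, since few fragments fall in them, and FPKM of near-identical genes depends on how shared reads were divided. A change in a few abundant genes shifts the FPKM of all others.

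No gene symbol occurred on more than 1 row. Genes with a mean FPKM of at least 1 over the 4 libraries were tested, 11039 in all. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and a mean-variance trend, group as the only term, and the Benjamini-Hochberg adjusted p under 0.05 as the threshold. Adjusted p-values of genes in the text are from limma unless another tool is named. A value at or below 1e-06 was counted as 0, a limit set after the values were seen. The numbers of genes at 0 per library count only values of exactly 0. No count test was used, since the values are not counts.

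Gene lists were tested with camera (limma) on the same fit with a preset correlation of 0.01, adjusted over the 22 lists with at least 3 tested members. The same lists were tested with an estimated correlation, on ranks and with fry. With an estimated correlation camera takes its degrees of freedom from the libraries instead of the genes, so so few libraries leave it little power. For each list the number of members passing was also counted with p adjusted over the list alone. The 23 lists were written before the data were examined, from general knowledge of the field: core and wider H3K27me3-imprinted genes, paternally and maternally expressed genes imprinted by DNA methylation, markers of trophectoderm, inner cell mass and epiblast, primitive endoderm, fibroblasts, oocytes, and cumulus and granulosa cells, 2-cell-stage genes, the Magea and Xlr clusters (with Mageb and Rhox genes), Y-linked genes, histone and DNA methylation enzymes, p53 targets, genes of the integrated stress response and unfolded protein response, glycolysis, respiratory chain, cholesterol synthesis, cell division, cytosolic ribosomal protein, FGF and ERK response genes, and YAP and TEAD targets. Whether the study itself picked some of these genes from these libraries is not known here, and where it did, a list's direction is not independent evidence.

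Genes named in the text followed a rule also fixed before the data were examined. It takes Xist and the core list, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap. Where fewer passed, places were filled up to 5 per direction by the smallest unadjusted p, and those genes are described as not passing. It then takes up to 4 members with the smallest unadjusted p of each list. Predicted genes, microRNAs and small nucleolar RNAs were skipped in the part on the largest changes. Further genes are named outside the rule, and not all are marked where they appear, such as Kdm4d, Eomes, Mageb16, Rhox1, Xlr4a, Mir3473d and Mir690.

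Chromosomes were taken by gene symbol or synonym from the RefSeq table of the GRCm38.p6 assembly, which placed 10954 of the 11039 tested genes. No coordinates are given, since that assembly is not the build the authors used. Intervals of medians are 95% bootstrap intervals over genes from 2000 draws, and genes are not independent replicates.

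The files hold no read counts, so the absolute depth is unknown. Relative depth was estimated from genes detected in both libraries whose mean over the 2 was under 0.5 FPKM. Among these the ratio of 2 libraries gathers at the ratio of what 1 fragment is worth. A fragment was worth 1.04 times as much FPKM in IVF library 1 as in SCNT library 1 (13.1% of 3592 low genes within 0.02 on the log2 scale of that ratio) and 0.975 times as much in IVF library 2 as in SCNT library 2 (6.82% of 4283). Across numbers the ratios were 1.18 for IVF 1 over IVF 2 (3.78% of 3755 low genes), 1.09 for SCNT 1 over SCNT 2, 1.15 for IVF 1 over SCNT 2 and 0.876 for IVF 2 over SCNT 1. Libraries of the same number were thus closest in this respect, which is why differences within each number are printed beside the list values.

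The steps were tested on data simulated for SCNT against IVF over the same 11039 genes, with 200 changed genes in each of 10 runs. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2, so the rates do not cover lower genes. No effect of the replicate number was simulated. Of the changed genes, 1.49% were recovered at a log2 change of 1, 52.2% at 2 and 72.0% at 3, and 3.24% of calls were unchanged genes. A list of 20 genes raised by 0.5 had a camera p under 0.05 in 10 of 10 runs and an unchanged list in 0 of 10. That p was not adjusted, unlike the p on which the reported lists were called, and smaller lists were not simulated. Simulated genes were independent of each other, which real genes of a list are not. The alternatives were other pseudocounts (0.1 and 5), no filter on low values and a filter at 5 FPKM, quantile normalization, scaling by the median ratio, limma without the trend or with a robust prior, the replicate number as a block, each library left out in turn, and the other list tests. After the data were seen, tests without microRNA and small nucleolar RNA genes and of the X chromosome without the Magea and Xlr list were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.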

Results

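RNA was sequenced from mouse early blastocysts made either by in vitro fertilization (IVF) or by somatic cell nuclear transfer (SCNT), in which the nucleus of a somatic cell replaces that of the oocyte. Each group had 2 libraries, each prepared from 6 pooled embryos lysed 96 hours after fertilization or activation. The IVF embryos came from Xist knockout oocytes of a 129S1 strain and wild-type CAST/EiJ sperm. The SCNT embryos received nuclei of embryonic fibroblasts, heterozygous for the Xist knockout, from a cross of a 129S1 mother and a CAST/EiJ father, and their recipient oocytes came from B6D2F1/J females. The values, for 23235 gene symbols, were taken to be FPKM, fragments mapped per kilobase of transcript and scaled to the mapped total. That unit is inferred. FPKM summed to 933167 and 985197 in IVF libraries 1 and 2 and to 956773 and 976790 in SCNT libraries 1 and 2. Between 10802 and 10923 genes per library reached 1 FPKM. The absolute depth is unknown, so the counting error of the values here cannot be given. Genes listed at exactly 0 numbered 6527 and 6505 in the IVF and SCNT libraries numbered 1, against 5716 and 5212 in those numbered 2. The libraries thus also differed by number. Differences within each number are therefore given beside the group differences, as pair 1 (SCNT 1 minus IVF 1) and pair 2 (SCNT 2 minus IVF 2). Nothing in the labels says that the libraries of a group came from separate parents or days, so p-values measure only the spread between these libraries, which may be technical. Changes are on the log2(FPKM + 1) scale as SCNT minus IVF, which understates the change of low genes.

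Xist, the non-coding RNA that silences an X chromosome and the gene knocked out on a parental allele, was listed at 1.09 and 13.9 FPKM in the IVF libraries and at 4.13 and 3.33 FPKM in the SCNT libraries. The IVF libraries enclosed the SCNT values, and the difference of -0.25 ± 0.91 (SE) was not larger than the spread between replicates (limma adjusted p = 0.9996). The difference was 1.30 in pair 1 and -1.79 in pair 2. Without IVF library 1 the difference was -1.66, and without IVF library 2 it was 1.17. Which part of Xist the knockout removes and the sex of the embryos are not given in the sources used here, so these values do not check the genotype. Tsix, outside the naming rule but transcribed across Xist from the opposite strand, was listed at 0.662 and 0.961 FPKM in IVF and at 2.19 in both SCNT libraries, and reads of the overlapping pair cannot be told apart unless strand was used.

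The title of the series asks whether imprinting by H3K27me3, a repressive histone mark that silences the maternal allele of some genes, is defective in SCNT embryos. All 5 genes of the core list of H3K27me3-imprinted genes had higher FPKM in both SCNT libraries than in both IVF libraries. Slc38a4, an amino acid transporter gene on chromosome 15, rose from 24.0 ± 1.33 to 55.7 ± 8.78 FPKM (mean ± SD, 2 libraries per group), a ratio of 2.32. Sfmbt2, a Polycomb-group gene on chromosome 2, rose from 20.5 ± 7.48 to 40.3 ± 3.25 FPKM, and Gab1, a signalling adaptor gene on chromosome 8, rose from 14.4 ± 2.50 to 23.6 ± 4.11 FPKM. Smoc1, which encodes a secreted calcium-binding matrix protein and lies on chromosome 12, rose from 2.87 ± 0.606 to 4.71 ± 0.442 FPKM. Phf17 on chromosome 3, also named Jade1, had 15.4 ± 1.98 FPKM in IVF and 21.0 ± 2.34 FPKM in SCNT and did not pass the test.

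The log2 differences were 1.17 ± 0.19 (SE) for Slc38a4, 0.98 ± 0.28 for Sfmbt2, 0.67 ± 0.22 for Gab1, 0.57 ± 0.20 for Smoc1 and 0.43 ± 0.19 for Phf17. With limma, 4 of the 5 genes passed at an adjusted p under 0.05 when adjusted over the list alone (0.00831, 0.0436, 0.0461 and 0.0474, against 0.0758 for Phf17). None passed when adjusted over all 11039 tested genes, where 4 of the 5 had an unadjusted p under 0.05. As a group the core genes rose, with a median of 0.67, 0.68 in pair 1 and 0.67 in pair 2 (camera adjusted p = 1.43e-05). The p with an estimated correlation was 0.0739 before and 0.568 after adjustment over the lists. The number of core genes passing over the list alone fell to 3 without IVF library 1, 2 without IVF library 2, 0 without SCNT library 1 and 1 without SCNT library 2, while camera's adjusted p stayed under 0.05 each time. Markers of trophectoderm, the outer layer of the blastocyst, also rose as a group by a median of 0.17, a call that was lost with an estimated correlation (adjusted p = 0.720), without IVF library 2 (0.199) and without SCNT library 1 (0.172).

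**Figure D1:**
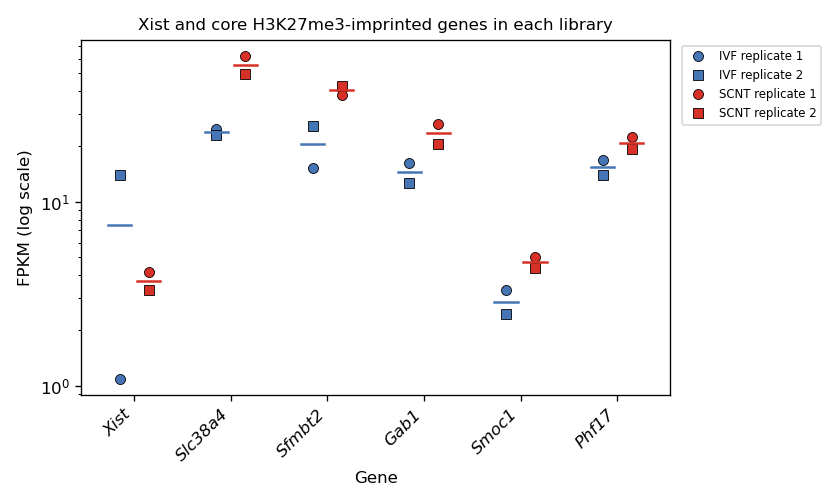
FPKM on a log axis of Xist and of the 5 core H3K27me3-imprinted genes in each of the 4 libraries (blue IVF, red SCNT; circles replicate 1, squares replicate 2; short lines are group means). Both SCNT libraries lie above both IVF libraries for each core gene, as for Slc38a4 with 61.9 and 49.5 against 24.9 and 23.0 FPKM, while the IVF values of Xist, 1.09 and 13.9 FPKM, lie on both sides of the SCNT values.

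A wider list of 15 candidate genes for H3K27me3 imprinting had 11 tested members, and these rose as a group with a median of 0.33 (camera adjusted p = 0.00948). The adjusted p with an estimated correlation was 0.568. Slc38a1, an amino acid transporter gene of the same family as Slc38a4 and also on chromosome 15, rose from 6.01 and 5.81 FPKM in IVF to 11.2 and 11.6 FPKM in SCNT and alone passed when adjusted over the list alone (limma adjusted p = 0.0375). Mbnl2, an RNA splicing regulator, differed by 0.59, Rbms1 by 0.62 and Tle3, a transcriptional corepressor, by 0.62, none of them past the threshold. Of the 11 genes, 9 had higher and 2 lower estimates, and the medians were 0.13 in pair 1 and 0.22 in pair 2. The group call was lost without IVF library 2 (median 0.25, adjusted p = 0.149) and without SCNT library 1 (0.37, adjusted p = 0.0686).

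Genes imprinted by DNA methylation did not move one way. Of 11 tested paternally expressed genes, Impact, an inhibitor of the kinase Gcn2 encoded on chromosome 18, fell from 15.5 ± 1.97 to 4.24 ± 1.33 FPKM and passed when adjusted over the list alone (log2 difference -1.67 ± 0.24, limma adjusted p = 0.0103). The other 10 did not pass, among them Mest at -0.75, Snrpn at -0.42 and Airn at 0.58. Airn overlaps Igf2r on the opposite strand, so its reads are uncertain where strand was not used. The list's median was -0.08 (camera adjusted p = 0.141), with -0.24 in pair 1 and -0.13 in pair 2. It passed the threshold without IVF library 1 (median -0.36, adjusted p = 0.0199) and without SCNT library 2 (-0.30, adjusted p = 0.0110), while the median turned to 0.0066 without IVF library 2 (adjusted p = 0.926) and to 0.087 without SCNT library 1 (adjusted p = 0.740). None of 14 tested maternally expressed genes passed over the list alone with limma, where 2 had an unadjusted p under 0.05. H19 was listed at 0.845 and 0.748 FPKM in IVF and at 7.97 and 3.38 FPKM in SCNT (log2 difference 1.80 ± 0.37, limma adjusted p = 0.0598 over the list alone); over all genes it passed without SCNT library 2 (adjusted p = 0.0318). In the same list Grb10, Osbpl5 and Cdkn1c differed by -0.57, 0.47 and -0.67. The maternally expressed list had a median of -0.10 (camera adjusted p = 0.594), -0.01 in pair 1 and -0.03 in pair 2.

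Across the transcriptome, 8 genes were higher and 6 lower in SCNT at a limma adjusted p under 0.05, and all 14 changed at least 2-fold. Of these, 11 were microRNA or small nucleolar RNA genes, 6 higher and 5 lower, each listed at 0 in both libraries of a group. Snord69, for example, was listed at 694 and 634 FPKM in SCNT and at 0 in both IVF libraries, and Snord42b at 1724 and 1459 FPKM in IVF and at 0 in both SCNT libraries; these 2 examples were picked after their values were seen. Among all 205 tested short RNA genes, 14 were at 0 in both libraries of 1 group and above 0 in both of the other, and the other 2 ways of pairing the 4 libraries gave 14 (libraries 1 against libraries 2) and 10 such genes. BC051665 on chromosome 13 rose from 5.49 ± 1.29 to 95.1 ± 13.2 FPKM, a ratio of 17.3 (log2 difference 3.90 ± 0.22, adjusted p = 0.00903), and did not pass when no filter on low values was used (adjusted p = 0.0720, against 0.00201 to 0.0266 under the other alternatives). The predicted genes 4930461G14Rik (log2 difference 3.34, adjusted p = 0.0448) and 4930550L24Rik (-3.35, adjusted p = 0.0265) completed the 14; both are outside the naming rule and are named because they were called. The call of 4930461G14Rik was lost with a pseudocount of 5, without a filter, with the filter at 5 FPKM and under both scalings (adjusted p of 0.0573 to 0.366), and that of 4930550L24Rik without a filter (adjusted p = 0.230). At an unadjusted p under 0.05 there were 783 genes, 469 higher and 314 lower, where chance alone gives 552. With the replicate number as a block there were 1832. The groups did not overlap for 2024 genes that were higher and 1662 that were lower, and chance gives such a separation for 33.3% of genes. Leaving out 1 library raised the number of called genes to between 45 and 53, and all 14 were called each time.

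The genes next in rank did not pass over all genes. Tspan1, a tetraspanin gene, had 4.37 ± 0.0736 FPKM in IVF and 27.7 ± 8.72 FPKM in SCNT (adjusted p = 0.119). Entpd1, which encodes an enzyme that hydrolyses extracellular ATP, differed by 1.53 ± 0.17, the membrane protein gene Praf2 by 1.63 ± 0.19, and Serpina3m, a protease inhibitor gene, by 1.88 ± 0.23, with adjusted p of 0.123, 0.123 and 0.140. In the other direction, Rbp2, a cellular retinol-binding protein gene, had 10.1 ± 0.245 FPKM in IVF and 1.64 ± 0.262 FPKM in SCNT (adjusted p = 0.0529). Tuba3b, an alpha-tubulin gene whose reads can be shared with its near-identical copy Tuba3a, had 14.5 ± 0.799 and 2.25 ± 0.614 FPKM (adjusted p = 0.0646). Magea5 differed by -2.83 ± 0.29 (adjusted p = 0.102), the fatty acid-binding protein gene Fabp9 by -2.41 ± 0.27 and Xlr4b by -1.72 ± 0.20 (adjusted p = 0.123 for both). With the microRNA and small nucleolar RNA genes left out of the test, an alternative chosen after seeing the data, Rbp2, Tuba3b and Magea5 passed and 6 genes were called in all. Praf2 and Magea5 passed with the replicate number as a block (limma adjusted p = 0.0374 for both). The robust prior brought Tspan1, Rbp2, Tuba3b, Magea5 and Fabp9 past the threshold. Leaving out a library brought some of these genes past the threshold: Tspan1, Magea5 and Fabp9 without SCNT library 2 (adjusted p = 0.0190, 0.0351 and 0.0313), Magea5 and Tuba3b without SCNT library 1 (0.0142 and 0.0446), Serpina3m and Tuba3b without IVF library 1 (0.0376 and 0.0441), and Fabp9 without IVF library 2 (0.0473).

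Gene lists written before the data were examined gave the state of lineages, other cell types, metabolism and stress. Of 23 lists, 22 had at least 3 tested members, and 9 passed at a camera adjusted p under 0.05 with the preset correlation of 0.01, 6 higher and 3 lower in SCNT. With an estimated correlation none passed (0 of 22 had an unadjusted p under 0.05, and the lowest adjusted p was 0.568). That test has few degrees of freedom with so few libraries. A call lost there does not by itself show that correlation between genes undid it. The wider H3K27me3 candidates had an estimated correlation of -0.07, below the preset 0.01, yet camera's unadjusted p rose from 0.00388 to 0.0939. In the other called lists the estimate was above the preset. It was 0.67 for cholesterol synthesis, 0.37 for Magea and Xlr, 0.33 for primitive endoderm, 0.31 for the respiratory chain and 0.22 for the core genes. For trophectoderm, stress response genes and p53 targets it was 0.17, 0.14 and 0.030. If genes are that correlated, the p with the preset is too small, though these estimates rest on few libraries. With fry, which asks whether the members of a list move one way on balance, none passed either, with a lowest adjusted p of 0.251, although the core list and the p53 list had unadjusted p of 0.0228 and 0.0114. The share of summed FPKM in microRNA and small nucleolar RNA genes was 12.4% and 12.2% in the IVF libraries and 9.50% and 9.73% in the SCNT libraries, so it moved with the group beside every list.

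**Figure D2:**
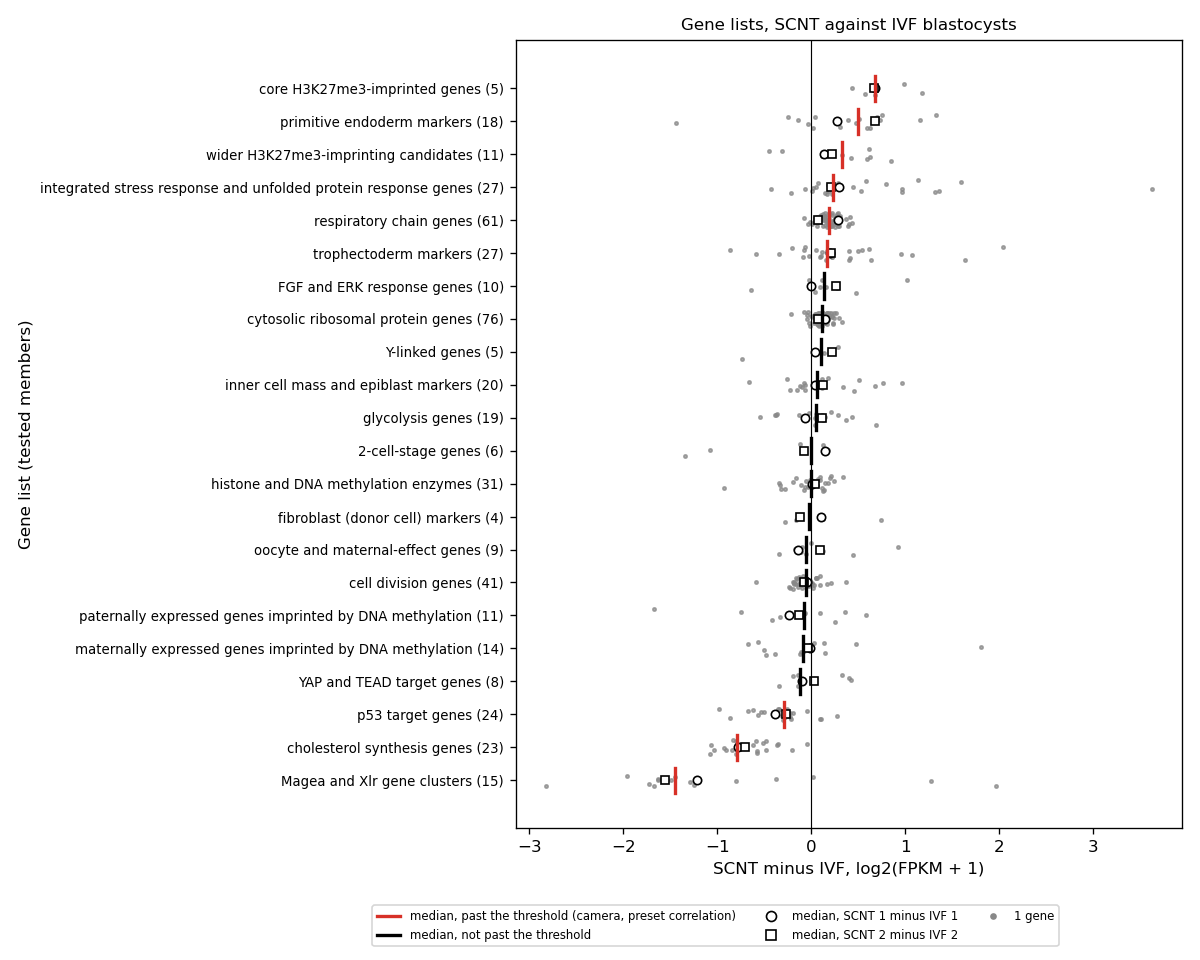
SCNT minus IVF differences in log2(FPKM + 1) for each tested gene (grey points) of 22 gene lists, with the list median as a bar (red past the camera threshold with the preset correlation, black not) and the medians of pair 1 (circles) and pair 2 (squares); tested members are in brackets. The core H3K27me3-imprinted genes have the highest median, 0.67, and the Magea and Xlr clusters the lowest, -1.45.

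Trophectoderm markers rose as a group, with all 27 members tested and a median of 0.17, 0.20 in both pairs (camera adjusted p = 0.00827). With an estimated correlation the adjusted p was 0.720. When adjusted over the list alone, 3 markers rose, 1 fell and 23 did not pass. Elf5, a transcription factor gene of trophoblast, rose from 3.56 ± 0.461 to 13.7 ± 5.97 FPKM, the keratin gene Krt19 from 1.63 ± 0.631 to 10.4 ± 5.60 FPKM and the tetraspanin gene Tspan8 from 198 ± 30.8 to 414 ± 28.4 FPKM, while Lrp2, which encodes the endocytic receptor megalin, fell from 68.6 ± 9.51 to 37.1 ± 2.97 FPKM. None of these 4 passed over all genes, although Krt19 did without SCNT library 2 (limma adjusted p = 0.0440). The trophectoderm regulators Cdx2 and Gata3 differed by 0.63 and 0.09 and did not pass; these 2 were picked as familiar markers after their values were seen. The group call was lost without IVF library 2 (median 0.07, adjusted p = 0.199) and without SCNT library 1 (0.02, adjusted p = 0.172), and the median was 0.31 without IVF library 1 or SCNT library 2. The 4 genes passing over the list alone became 0 without IVF library 1, IVF library 2 or SCNT library 1, and 3 without SCNT library 2.

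Primitive endoderm markers also rose as a group, with 18 of 23 tested and a median of 0.49, 0.27 in pair 1 and 0.68 in pair 2 (camera adjusted p = 0.000178). With an estimated correlation the adjusted p was 0.718. No member passed over the list alone with limma, while 6 had an unadjusted p under 0.05, and 14 of the 18 estimates were higher and 4 lower. The matrix glycoprotein gene Sparc had 31.5 ± 5.18 FPKM in IVF and 71.6 ± 12.1 FPKM in SCNT, and the laminin genes Lama1 and Lamc1 and the collagen chaperone gene Serpinh1 differed by 0.69, 0.73 and 0.75. Most of these genes encode or process basement membrane, which other cells also make. The 4 lower estimates, outside the naming rule, were those of Cited1 (-1.44), Gata6 (-0.25), Col4a1 (-0.14) and Sox17 (-0.04). Gata4, also outside the rule, differed by 0.62. The median was 0.32 without SCNT library 2, and over the list alone 1 member passed as higher without SCNT library 1 and 1 as lower without SCNT library 2. Inner cell mass and epiblast markers did not pass, with 20 tested and a median of 0.05, 0.04 in pair 1 and 0.12 in pair 2 (camera adjusted p = 0.295). None of them passed over the list alone with limma, where 2 had an unadjusted p under 0.05: Spp1, which encodes osteopontin, with a difference of 0.96, and Tdh, threonine dehydrogenase, with 0.76. Tdgf1 and Gdf3 differed by 0.67 and 0.34.

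The list of the Magea and Xlr clusters, families of X-linked genes expressed mainly in germ cells and in tumours, fell as a group. Its tested members include Mageb16 and 3 genes of another X-linked family, Rhox1, Rhox6 and Rhox9, which were the 3 members with higher estimates. Of 15 tested genes, 11 fell, 1 rose and 3 did not pass when adjusted over the list alone, and the median was -1.45, with -1.21 in pair 1 and -1.56 in pair 2 (camera adjusted p = 3.41e-10). The adjusted p with an estimated correlation was 0.568, and none of the 15 passed over all genes, where 12 had an unadjusted p under 0.05. Magea5 had 12.2 ± 1.71 FPKM in IVF and 0.905 ± 0.647 FPKM in SCNT, and Magea8 had 6.63 ± 1.39 and 0.995 ± 0.621 FPKM. Xlr4b fell from 6.97 ± 0.894 to 1.41 ± 0.240 FPKM and Xlr3c from 5.18 ± 2.49 to 0.910 ± 0.138 FPKM. Copies of Xlr, and of Magea, are nearly identical, so reads can be shared between members and their values are not independent. The 1 gene that rose, Rhox6, was outside the naming rule; it was listed at 0 and 1.55 FPKM in IVF and at 4.05 and 6.70 FPKM in SCNT. Rhox9, also outside the rule, was listed at 0 and 0.856 FPKM in IVF and at 1.12 and 4.10 FPKM in SCNT and did not pass. Without IVF library 2 there were 2 members higher over the list alone, and without SCNT library 1 there were 3.

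**Figure D3:**
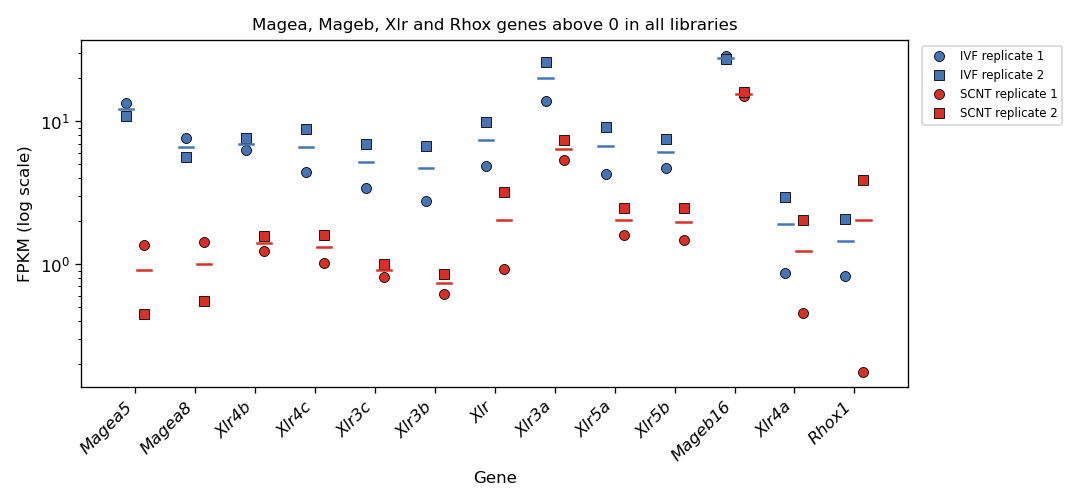
FPKM on a log axis of the 13 tested genes of the Magea and Xlr list that were above 0 in all 4 libraries (blue IVF, red SCNT; circles replicate 1, squares replicate 2; short lines are group means). For 11 of the 13 both SCNT libraries lie below both IVF libraries, as for Magea5 with 1.36 and 0.447 against 13.4 and 11.0 FPKM, while for Xlr4a and Rhox1 the groups overlap. Rhox6 and Rhox9, at 0 in IVF library 1 and so not on the log axis, are the 2 tested members with both SCNT libraries above both IVF libraries.

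The X chromosome as a whole did not follow these clusters. The 350 tested X-linked genes, by chromosome in the RefSeq annotation of GRCm38, had a median difference of 0.04 (95% bootstrap interval over genes 0.0032 to 0.072) against 0.01 for 10598 autosomal genes, and the X-linked set did not pass (camera with the preset correlation, p = 0.996). Without the members of the Magea and Xlr list, an alternative added after seeing the data, 335 genes had a median of 0.05 (camera with the preset correlation, p = 0.457). The X-linked medians were 0.09 in pair 1 and 0.01 in pair 2. Without IVF library 1 the set was lower in SCNT (median -0.04, p = 0.00915 with the preset correlation), and without IVF library 2 it was higher (0.12, p = 0.0275), so the direction depended on which IVF library was used. The sex of the embryos and of the donor cells is not given in the sources used here, so the mix of sexes may differ between pools. That mix bears on Xist, X-linked and Y-linked values alike and was not tested. Of the Y-linked list, 5 genes were tested and none passed over the list alone with limma (1 at an unadjusted p under 0.05). Ube1y1 had 2.81 ± 0.177 FPKM in IVF and 1.30 ± 0.239 FPKM in SCNT, Eif2s3y had 46.9 ± 3.41 and 51.7 ± 8.25 FPKM, and Uty and Kdm5d differed by 0.28 and 0.10. The Y-linked median was 0.10, its mean -0.04 and its camera direction lower (adjusted p = 0.896), with medians of 0.04 in pair 1 and 0.22 in pair 2.

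Cholesterol synthesis genes fell as a group. All 23 tested members had lower estimates in SCNT, with a median of -0.79, -0.78 in pair 1 and -0.71 in pair 2 (camera adjusted p = 1.15e-11). Under an estimated correlation the adjusted p was 0.667. With limma none passed over the list alone, and 8 had an unadjusted p under 0.05. The squalene synthase gene Fdft1 had 105 ± 19.3 FPKM in IVF and 55.0 ± 7.58 FPKM in SCNT, the mevalonate kinase gene Mvk 109 ± 27.9 and 50.9 ± 9.44 FPKM, the methyl sterol oxidase gene Sc4mol 104 ± 11.7 and 60.0 ± 6.71 FPKM, and the sterol carrier gene Stard4 11.4 ± 0.605 and 6.11 ± 0.325 FPKM. The median shrank to -0.35 without IVF library 1 and to -0.43 without SCNT library 2, and 13 members passed over the list alone without IVF library 2.

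Respiratory chain genes rose slightly as a group, with 58 of 61 tested members higher and a median of 0.19 (camera adjusted p = 0.00110). The adjusted p with an estimated correlation was 0.720, and with limma no member had an unadjusted p under 0.05. The succinate dehydrogenase gene Sdhd differed by 0.43, the ATP synthase gene Atp5e by 0.39, the complex I gene Ndufa3 by 0.40 and the cytochrome c gene Cycs by 0.37. The median was 0.29 in pair 1 and 0.07 in pair 2. The call was lost without SCNT library 2 (median 0.15, adjusted p = 0.103) and without IVF library 1 (0.0086, adjusted p = 0.921, with camera's direction turned to lower), and the median was 0.35 without IVF library 2. Glycolysis genes did not pass, with 19 tested, a median of 0.05, -0.07 in pair 1 and 0.11 in pair 2 (camera adjusted p = 0.865), and Tpi1, Pgam1, Ldha and Pfkp differed by 0.69, 0.37, -0.37 and -0.39. The 76 cytosolic ribosomal protein genes had a median of 0.11, 0.15 in pair 1 and 0.07 in pair 2, and did not pass (camera adjusted p = 0.0897); Rps23, Rps15a, Rpl10 and Rpl24 differed by 0.33, 0.21, 0.23 and 0.24. That list passed on ranks (adjusted p = 0.00534), without the trend (adjusted p = 0.0320), with the replicate number as a block (adjusted p = 4.64e-05), without IVF library 1 (median 0.20, adjusted p = 0.0404) and without SCNT library 2 (0.27, adjusted p = 0.00146), while the median was 0.0077 without IVF library 2 (adjusted p = 0.949) and -0.023 without SCNT library 1 (adjusted p = 0.527).

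Genes of the integrated stress response and the unfolded protein response, which cells induce when amino acids run short or proteins misfold, rose as a group. Of 27 tested genes, 24 had higher estimates, with a median of 0.23, 0.29 in pair 1 and 0.20 in pair 2 (camera adjusted p = 1.43e-05). The adjusted p with an estimated correlation was 0.587. With limma none passed over the list alone, and 7 had an unadjusted p under 0.05. Ddit3, which encodes the transcription factor Chop, had 30.1 ± 11.5 FPKM in IVF and 90.9 ± 23.6 FPKM in SCNT, the proline synthesis gene Aldh18a1 5.81 ± 1.27 and 16.2 ± 5.32 FPKM, the pseudokinase gene Trib3 4.03 ± 0.469 and 12.4 ± 5.54 FPKM, and Sdf2l1, of the endoplasmic reticulum, 16.6 ± 1.98 and 29.4 ± 3.31 FPKM. The mean was 0.54, and the highest difference was that of Nupr1 (3.62), which was named for that reason; it had 2.03 ± 1.37 FPKM in IVF and was listed at 110 and 10.3 FPKM in SCNT, so that 1 SCNT library set its size. The median was 0.14 without SCNT library 1 and 0.36 without IVF library 1, and 6 members passed over the list alone without SCNT library 2 and 1 without IVF library 2.

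Targets of the tumour suppressor p53 fell as a group, with 21 of 24 tested genes lower and a median of -0.29, -0.39 in pair 1 and -0.27 in pair 2 (camera adjusted p = 4.45e-06). The p with an estimated correlation was 0.0508 before and 0.568 after adjustment over the lists. With limma none passed over the list alone, and 4 had an unadjusted p under 0.05. These were the cell cycle inhibitor gene Cdkn1a, with 94.6 ± 22.2 FPKM in IVF and 49.3 ± 21.7 FPKM in SCNT, the cyclin G1 gene Ccng1, with 109 ± 17.0 and 60.4 ± 17.2 FPKM, Trp53inp1, with a difference of -0.67, and the kinase gene Plk2, with -0.53. The 41 tested cell division genes had a median of -0.06, -0.04 in pair 1 and -0.08 in pair 2, and did not pass (camera adjusted p = 0.180); the median was -0.18 without SCNT library 1 (adjusted p = 0.0634), -0.11 without IVF library 2 and -0.018 without SCNT library 2. Gins1, Ccne1, Nusap1 and Tyms differed by 0.36, -0.59, -0.24 and 0.21.

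Markers of other cells that the embryos or donor nuclei could bring gave no group call. Only 4 of 30 fibroblast markers reached the filter on low values, with a median of -0.02, 0.10 in pair 1 and -0.13 in pair 2 (camera adjusted p = 0.896). The collagen gene Col1a1 was listed at 0.730 and 0.0846 FPKM in IVF and at 3.38 and 0.193 FPKM in SCNT, so the highest value came from 1 library, and Fn1, Igfbp7 and Tagln differed by -0.29, -0.17 and 0.13. This list had a mean of 0.10 against a camera direction of lower, and it passed as lower without SCNT library 1 (median -0.49, adjusted p = 0.0470). Oocyte and maternal-effect genes, with 9 tested, had a median of -0.06, -0.14 in pair 1 and 0.10 in pair 2, but a mean of 0.08 and a camera direction of higher (adjusted p = 0.896). Ooep, a gene of the subcortical maternal complex, had 25.3 ± 5.90 FPKM in IVF and 50.6 ± 22.1 FPKM in SCNT and did not pass, and Oas1d, H1foo and Cnot7 differed by 0.44, -0.35 and -0.18. Of the cumulus and granulosa cell markers only Amhr2 and Hsd17b1 passed the filter on low values, too few for a test of the list, with differences of 0.64 and 0.36 that did not pass.

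The remaining lists did not pass either. Genes of the 2-cell stage, with 6 tested, had a median of 0.00015, a mean of -0.35 and a camera direction of lower (adjusted p = 0.635), with medians of 0.15 in pair 1 and -0.08 in pair 2. Among them Sp110 had 80.0 ± 35.2 FPKM in IVF and 37.6 ± 18.5 FPKM in SCNT, Tdpoz4 was listed at 0.107 and 9.29 FPKM in IVF against 0.204 and 0.468 FPKM in SCNT, and Pramel7 and Eif1a differed by 0.14 and 0.13. Without IVF library 1 this list passed as lower (median -0.29, adjusted p = 0.00443), and so did Tdpoz4 over all genes (limma adjusted p = 0.0125). The 31 tested histone and DNA methylation enzymes had a median of -0.0052, 0.01 in pair 1 and 0.03 in pair 2 (camera adjusted p = 0.800). The H3K4 demethylase gene Kdm5b had 33.4 ± 6.95 FPKM in IVF and 17.1 ± 3.82 FPKM in SCNT and did not pass, and Kdm5c, Kdm5a and Tet2 differed by -0.34, 0.33 and -0.33. FGF and ERK response genes, with 10 tested, had a median of 0.13, -0.00057 in pair 1 and 0.26 in pair 2 (camera adjusted p = 0.215), and passed without IVF library 1 (0.41, adjusted p = 0.0277). That list's median turned to -0.054 without IVF library 2 (adjusted p = 0.949) and was 0.043 without SCNT library 1 (adjusted p = 0.581). In that list the phosphatase gene Dusp6 differed by 1.02, Ier3 by -0.64, Fos by 0.48 and Spry2 by 0.25. The 8 tested YAP and TEAD targets had a median of -0.13, -0.10 in pair 1 and 0.03 in pair 2, but a mean of 0.03 and a camera direction of higher (adjusted p = 0.896), with Lats2, Tead1, Cyr61 and Ctgf at 0.40, 0.42, 0.33 and -0.34.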

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

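The tests without microRNA and small nucleolar RNA genes and the test of the X chromosome without the Magea and Xlr list were chosen after the data were seen; all others were planned. In all, 18 alternatives were run. Of 1358 values of the 99 named genes other than Xist, 1350 kept their sign, and 10 of these genes passed the threshold in some alternative but not in the reported fit. Under the pseudocounts of 0.1 and 5, the filter at 5 FPKM, quantile normalization, median-ratio scaling, and limma without the trend, 17, 13, 12, 13, 13 and 14 genes were called, of which 14, 13, 12, 13, 13 and 14 were among the reported 14. Scaling moved the median of all genes from 0.013 to -0.0025 and -0.0058. Without a filter on low values 5 genes were higher instead of 8, with 19748 genes tested: BC051665 (adjusted p = 0.0720), 4930461G14Rik (0.366), 4930550L24Rik (0.230) and Mir3473d (0.0553) lost their calls. With the pseudocount of 5, the filter at 5 FPKM, quantile normalization and median-ratio scaling 4930461G14Rik lost its call (0.125, 0.196, 0.0599 and 0.0573), and with that filter so did Mir690 (0.0540). The cause was not tested. The robust prior called 21 genes, the reported 14 among them, with 12 lower instead of 6; Fabp9, Magea5, Rbp2, Tspan1 and Tuba3b then passed, as Rbp2 also did with the pseudocount of 0.1. Without the short RNA genes 2 were higher and 6 changed at least 2-fold, 11 of the calls being left out. Magea5, Rbp2 and Tuba3b then passed, and 845 instead of 783 genes had an unadjusted p under 0.05 although fewer were tested, so the refit changed the p themselves; why was not tested. Leaving out 1 library gave 15 to 31 genes higher, 14 to 34 lower and 45 to 53 changed at least 2-fold; the lone library of a group is then assumed to vary like the other group, and the cause was not tested. The absolute depth is unknown, so what it limits cannot be given. With 2 libraries per group the simulation recovered 1.49% of changed genes at a log2 change of 1, 52.2% at 2 and 72.0% at 3. These rates are for genes with a mean log2(FPKM + 1) above 2 and do not cover lower genes.

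With an estimated correlation and with fry, none of the 9 called lists passed; medians are not altered by the test. Adjusted p was 0.568 and 0.251 for the core H3K27me3-imprinted genes (median 0.67), 0.568 and 0.815 for the wider candidates (0.33), 0.720 and 0.664 for trophectoderm (0.17), 0.718 and 0.543 for primitive endoderm (0.49), and 0.587 and 0.543 for the stress response genes (0.23). It was 0.720 and 0.815 for the respiratory chain (0.19), 0.568 and 0.522 for Magea and Xlr (-1.45), 0.568 and 0.251 for p53 targets (-0.29), and 0.667 and 0.664 for cholesterol synthesis (-0.79). With an estimated correlation camera has few degrees of freedom in this design, so that loss says little about correlation between genes. Why fry called none was not tested.

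Some lists not past the threshold in the reported fit turned direction, and the cause was not tested. Without a filter on low values the fibroblast median was 0.052 and the oocyte median -0.017. On ranks camera's direction turned for the oocyte list (median -0.055), the Y-linked genes (0.10) and the YAP and TEAD targets (-0.13), the last pair also with the replicate block (medians 0.10 and -0.13).

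Leaving out each library in turn gave ranges of the median: 0.0086 to 0.35 for the respiratory chain, 0.021 to 0.31 for trophectoderm, 0.25 to 0.46 for the wider candidates, -0.29 to 0.26 for 2-cell-stage genes, -0.023 to 0.27 for ribosomal protein genes, -0.49 to 0.19 for fibroblast markers, -0.15 to 0.30 for glycolysis, -0.10 to 0.10 for methylation enzymes, -0.22 to -0.015 for maternally and -0.36 to 0.087 for paternally expressed genes, -0.054 to 0.41 for FGF and ERK response genes, -0.18 to -0.018 for cell division genes, -0.10 to 0.0057 for oocyte genes, -0.036 to 0.083 for inner cell mass and epiblast markers, 0.053 to 0.14 for Y-linked genes, -0.097 to 0.010 for YAP and TEAD targets and -0.043 to 0.12 for X-linked genes. Xist ranged from -1.66 to 1.17. Among named genes past the threshold in none of these fits, Eif1a ranged from -0.0045 to 0.26, Eif2s3y from -0.031 to 0.29, Fn1 from -0.65 to 0.082, Igfbp7 from -0.41 to 0.072, Pramel7 from -0.016 to 0.30 and Tagln from -0.049 to 0.58. The cause was not tested.

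The labels number the libraries 1 and 2 in both groups without saying that a number pairs them. Deviations from the group means correlated at 0.309 between libraries of the same number. Whole libraries correlated at 0.953 for IVF 1 with SCNT 1 and at 0.956 for IVF 2 with SCNT 2. Within groups it was 0.946 for IVF and 0.954 for SCNT, and 0.937 and 0.942 where both group and number differed. The number thus set libraries apart about as much as the group. With the replicate number as a block, 20 genes were called, among them all 14 reported, and 1832 instead of 783 had an unadjusted p under 0.05. Magea5, Praf2 and the ribosomal protein list (adjusted p = 4.64e-05) then passed, and no list lost its call.

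Keeping the highest of several rows per symbol gave nothing to compare, since no symbol was repeated. Tests of allele shares and of read counts were not run on these values.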

Other observations

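The tests of the trophectoderm share and of the second allele, and the calls without short RNA genes, were chosen only after the results were seen; the list of 50 germline genes below was written after the Magea and Xlr result but before the values of its members were examined, although Tuba3a in it is a near-identical copy of Tuba3b, whose difference had been seen.

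Germline genes outside the X-linked clusters, mostly genes of meiosis and of the piRNA pathway that restrains transposons, were lower in SCNT as a group. Of the 50, 29 were tested, 24 with lower and 5 with higher estimates, and the median was -0.42, -0.33 in pair 1 and -0.60 in pair 2 (camera with the preset correlation, p = 2.95e-08). The p with an estimated correlation was 0.122 and fry's p was 0.137. No result with a library left out is given for this list, so its dependence on single libraries is not known. With limma 10 had an unadjusted p under 0.05, and none passed when adjusted over the list alone. The 4 with the smallest p were as follows. Hsf2bp, a meiotic recombination gene, had 13.3 ± 0.553 FPKM in IVF and 6.93 ± 1.42 FPKM in SCNT, Zcwpw1, a reader of histone methylation in meiosis, 3.74 ± 0.710 and 1.70 ± 0.102 FPKM, Tex19.1, which acts in the germline and placenta, 54.4 ± 6.85 and 29.4 ± 6.24 FPKM, and the meiotic chromosome axis gene Hormad1 8.31 ± 3.85 and 2.76 ± 0.280 FPKM (mean ± SD, 2 libraries per group).

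The fall of the Magea and Xlr clusters was set against a lower expression of the whole X chromosome and a fall shared with other germline genes. The first is argued against by the X-linked genes outside the list, whose median of 0.0468 (95% bootstrap interval 0.0149 to 0.0839) lay above the bound set for this explanation, 0.5 times the clusters' median of -1.45. For the second, the held-out germline median of -0.416 was lower as it required. Camera called it with the preset correlation, but neither camera with an estimated correlation nor fry did. Its 95% bootstrap interval, -0.688 to -0.133, spans the bound set against it of -0.363, 0.25 times the clusters' median, and the fall was 0.287 times theirs. It stays open as a hypothesis for a part of the fall. Also open are reads shared between near-identical copies, the different parents and oocyte strains of the groups, and the treatment that the column names of the SCNT libraries may point to, which were not tested.

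The rise of the core H3K27me3-imprinted genes was set against a larger share of trophectoderm cells, a difference in scale between libraries, and expression from a second allele alone. A larger trophectoderm share would raise the core genes about as much as trophectoderm markers only if the core genes were expressed mainly there, which was not tested. The core median exceeded that of the markers by 0.502 (95% bootstrap interval over genes 0.169 to 1.02, and 0.413 to 0.532 with each library left out). That gap is smaller than the SD of the markers' differences, 0.613. Lrp2 fell, while 4 of the 27 markers, Elf5, Krt19, Tspan8 and Eomes, had differences of at least the core median. Of these, Eomes did not pass over the list alone (limma adjusted p = 0.141). A larger share of trophectoderm, or of a part of it, therefore stays open. Primitive endoderm markers rose by a median of 0.49 (camera adjusted p = 0.000178 with the preset correlation), and a larger share of those cells was not tested. After quantile normalization the core median was still 0.651 (camera adjusted p = 1.61e-05). Over the alternatives the core list's adjusted p ran from 5.66e-06 to 0.568, the highest with an estimated correlation. Camera sets a list against all other genes, so a scale shared by all genes could hardly have ended that call. The median of all genes was 0.013 before and -0.0025 after normalization. The value before normalization lies far below the core median, which argues against a scale shared by all genes. The value after it follows largely from the normalization itself and is no evidence. A second active allele could at most give a ratio of 2 with all else equal, and Slc38a4 had 2.32 ± 0.274 (SE), too close to that bound for these libraries to tell. The maternal and paternal alleles were not measured in these values, so loss of imprinting stays open and untested, as do the strain backgrounds of the groups.

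Short RNA genes at 0 in 1 group made up most of the transcriptome-wide calls, and the explanation weighed was unstable FPKM of very short genes. With the real groups 14 tested short RNA genes were at 0 in both libraries of 1 group and above 0 in both of the other, libraries 1 against libraries 2 gave 14, and the remaining pairing gave 10. The real count is within 1.5 times either, the bound set in advance, which is consistent with unstable values. Libraries 1 and 2 also differ from each other, so the 14 of that pairing is no measure of chance. The 14 against 10 leaves a difference between the groups at these genes open, and it was not tested. Whether the reads listed there came from the short RNAs themselves or from longer transcripts that hold them was not tested either.

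The X-linked median minus the autosomal median of log2 values was -0.53 and -0.21 in IVF libraries 1 and 2, which had 1.09 and 13.9 FPKM of Xist. It was -0.49 and -0.38 in SCNT libraries 1 and 2, which had 4.13 and 3.33 FPKM. The mix of sexes in each pool is unknown.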
